A study of Campylobacter jejuni with 9 samples.

How the data were processed

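RNA-seq libraries of *Campylobacter jejuni* NCTC12661 were analysed from the tables deposited for 9 samples. Per the labels' protocols, short spirals and filaments were separated on a membrane filter, ribosomal RNA was depleted with a Ribo-Zero kit, directional libraries were made with the NEBNext Ultra kit, and these were sequenced on an Illumina HiSeq instrument. The growth text is the same for all samples, so harvest times of the exponential cultures are not given in the sources used here. Per the submitters' processing notes, CASAVA 1.8.2 and bcl2fastq 1.8.4 were used. The aligner, the counting program, its use of strand and its annotation release are not given in the sources used here.

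Each deposited file held 1667 genes of 1 chromosome with positions, and its counts, per the file headers, were total gene reads and unique gene reads. The total counts were analysed and the unique counts served as an alternative. The authors also deposited TPM, which summed to 1000000 in each library, and RPKM, whose library totals exceeded the sum of gene reads. Of those totals, genes made up 40.7%, 32.7% and 8.6% in exponential replicates 1, 2 and 3 and 25.3% to 30.8% in the stationary libraries. TPM and RPKM entered no test. A further deposited column of expression values repeated RPKM in 8 libraries and TPM in exponential replicate 3, and was not used. Gene symbols were those in the files, with numbered copies such as *flaA_1* kept apart. Of 932 distinct symbols, 540 also occur in the table of genes of strain NCTC11168. Coordinates are those in the files, counted from 1.

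Counts were tested in R 4.3.3 with edgeR 4.0.16, using TMM scaling, filterByExpr, and the quasi-likelihood F test with robust fitting. Benjamini-Hochberg adjustment was over all tested genes of a comparison, with a threshold of 0.05. All 9 libraries were fitted with a coefficient per group, and the 3 pairs of groups were compared. A fit to the 6 libraries of a pair was an alternative. Levels are TMM-scaled CPM (read counts per 1000000 of the scaled library total) as mean ± SD of 3 libraries, and fold changes are on the log2 scale with their standard errors. The scaling of CPM values was computed over all 9 libraries. Gene lists were tested with camera in limma 3.58.1 on voom values, with a preset correlation of 0.01 and with an estimated correlation, and adjusted over the lists. Of 26 lists, 24 had at least 4 tested genes in the 9-library fit and 23 in the fit to the stationary libraries. Lists were matched by gene symbol, so a gene that the files give under another name or a locus ID only was missed. DESeq2 1.42.0 and limma-voom were the other tools.

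The groups, tests, gene lists, rule for named genes and most alternatives were fixed before the data were examined. The rule took, per comparison, the 8 largest rises and 8 largest falls among genes past the threshold whose groups did not overlap, with a mean of at least 20 CPM in the higher group and a symbol. It added up to 4 members with the smallest adjusted p of each list described, and a set of fixed genes (*ftsZ*, *recA*, *flaA*, *katA*, *dnaK* and *csrA*). A fixed *minD* and *cmeA* were not analysed here. Between stationary and exponential spirals the rule gave 8 genes, since 8 of the 16 called had a locus ID only. In the 9-library fit it gave no gene between filaments and stationary spirals, so it was applied there to the 6-library fit, a choice made after the data were seen.

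Alternatives were other scalings (RLE size factors, upper quartile, total count), DESeq2, limma-voom, no filter, a stricter filter (at least 10 CPM in 3 libraries), the replicate number as a term, the libraries of a pair alone, and leaving out each library in turn. Added after the data were seen were unique reads, a quality weight per library, leaving out genes near 0 in exponential replicate 2, leaving out both stationary spiral replicate 3 and filament replicate 1, and all alternatives of the 6-library fit. No rRNA or tRNA genes were among the 1667, so keeping them in was not applicable, and neither were pseudocounts. Upper-quartile scaling moved the median of all genes by -0.23, -0.26 and -0.03 on the log2 scale between stationary and exponential spirals, filaments and exponential spirals, and filaments and stationary spirals. Total-count scaling moved it by -0.24, -0.53 and -0.29, and by -0.33 in the 6-library fit.

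The tests were checked on simulated counts drawn with the spread of each group, with 100 genes changed 2-fold and 100 changed 4-fold, averaged over 5 draws. In the 6-library fit of the stationary groups 45 of the 2-fold and 98.6 of the 4-fold genes were recovered, and 8.6 unchanged genes were called. In the 9-library fit of the same groups 0 and 0 were recovered, and 0.1% of unchanged genes had an unadjusted p under 0.05. In the 9-library fit 2 and 14.8 were recovered for filaments against exponential spirals, and 2.2 and 13.2 for stationary against exponential spirals. For those 2 comparisons the 6-library fits recovered 0 and 0. No recovered gene had the wrong sign. A shift of 1 on the log2 scale in ribosomal protein genes between the stationary groups was called in 5 of 5 draws, also with an estimated correlation. Simulated genes were drawn independently, so this does not show how the estimated correlation behaves for genes that vary together. Comparisons sharing the exponential libraries were simulated 20 times with unchanged groups. A first version of that simulation left out the error of the exponential mean and was replaced after its output was seen.

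Libraries differed in depth by as much as 402714 against 2157526 gene reads, and genes near the filter have the least precise values in exponential replicate 3. No pair of libraries held identical values or agreed within sampling noise, and each counted as 1 replicate, as labelled. The chi-square per degree of freedom was 7.77 between stationary spiral replicates 1 and 2 and 10.3 between filament replicates 2 and 3. It was 83.6 to 115 for the other pairs within these groups. A difference beyond sampling noise cannot show that libraries came from separate cultures. Reads were not counted by molecule, so sampling error of counts is a lower limit.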

Results

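RNA was sequenced from *Campylobacter jejuni* NCTC12661, a gut bacterium whose cells are mostly short helical rods, called spirals here. The libraries came from 3 kinds of cell, which were spirals in exponential growth, spirals in stationary phase and long filaments in stationary phase. Each group had 3 libraries that the labels describe as independent biological replicates. The deposited tables held read counts for 1667 genes on 1 chromosome, of which 1005 carried a gene symbol and 662 a locus ID only. Total gene reads were 2138163, 1314504 and 402714 in exponential spiral replicates 1, 2 and 3. They were 918230, 1291222 and 1189371 in the stationary spirals and 1319689, 1175067 and 2157526 in the filaments.

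The stationary libraries were close to each other within a group and the exponential libraries were not. Spearman correlation over genes ranged from 0.939 to 0.989 between stationary spirals and from 0.962 to 0.996 between filaments, but from 0.605 to 0.655 between exponential spirals. Stationary spiral replicate 3 correlated with filament replicate 1 at 0.938, much as with stationary spiral replicates 1 and 2 at 0.939 and 0.944. The biological coefficient of variation was 0.885 in exponential spirals, 0.323 in stationary spirals and 0.252 in filaments. In exponential replicate 1 the 10 most abundant genes held 6.52% of the gene reads, against 21.9% and 28.6% in exponential replicates 3 and 2. That share was 18.9% to 20.9% in stationary spirals and 27.7% to 28.3% in filaments. The transfer-messenger RNA gene *ssrA* held 0.406% to 0.829% of reads in exponential spirals, 1.86% to 2.07% in stationary spirals and 4.44% to 4.78% in filaments. It was among stable RNAs set beforehand as signs of RNA depletion and quality, not of biology.

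**Figure D1:**
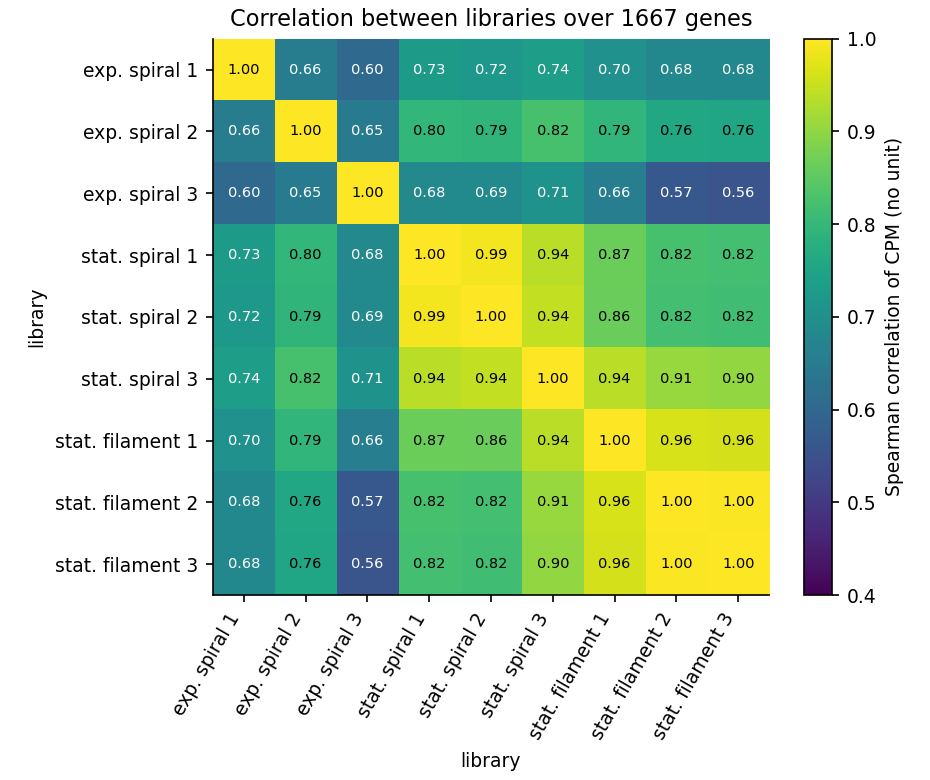
Spearman correlation of CPM (no unit) between every pair of the 9 libraries over 1667 genes, coloured from 0.4 to 1. The 3 exponential spiral libraries correlate at 0.605 to 0.655 with each other, below the 0.939 or more found within each stationary group.

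The first comparison asked how the transcripts of filaments differed from those of spirals in the same growth phase. *katA*, the gene of catalase, which breaks down hydrogen peroxide, rose from 2243 ± 2293 CPM in stationary spirals to 29010 ± 2011 CPM in filaments (mean ± SD, n = 3 each). Its log2 fold change was 3.71 with an SE of 0.70 and an adjusted p of 0.00572. *iutA* and *cirA*, whose *Escherichia coli* namesakes are outer-membrane receptors for iron-siderophore complexes, rose by log2 fold changes of 3.52 and 3.14. Their levels went from 235.3 ± 165.2 to 2665 ± 722.6 CPM and from 430.2 ± 177.5 to 3718 ± 917.2 CPM. Among genes with a symbol, the 5 others with the largest rises coded for ribosomal proteins, with log2 fold changes of 3.42 for *rplW*, 3.32 for *rplC*, 3.28 for *rpsJ*, 3.07 for *rplM* and 3.02 for *rpsI*. Several of these values depended on stationary spiral replicate 3, where *katA* was at 4891 CPM against 924.6 and 912.7 CPM in replicates 1 and 2. Without it the log2 fold change was 4.99 for *katA*, 4.26 for *iutA*, 4.49 for *rplW*, 4.60 for *rplC*, 4.81 for *rpsJ* and 3.78 for *rplM*.

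Among genes with a symbol the largest fall was that of *gltA*, the gene of citrate synthase, from 1387 ± 934.5 to 141.7 ± 31.78 CPM (n = 3 each), a log2 fold change of -3.23 with an adjusted p of 0.00621. *bsdB* fell by 3.22 and *regX3_1*, named as a response regulator, fell by 2.88 on the log2 scale. The γ-glutamyltranspeptidase gene *ggt* fell by 2.73, from 2588 ± 1678 to 374.3 ± 79.83 CPM. *rnhB* (ribonuclease HII) fell by 2.67, *rsmG* (a ribosomal RNA methyltransferase) by 2.66, *ctb* (a truncated globin) by 2.62 and *lldP* (a lactate permease) by 2.60. Stationary spiral replicate 3 lay nearer to the filaments for *gltA*, at 315.3 CPM against 2034 and 1810 CPM, for *ggt*, at 679 CPM against 3827 and 3258 CPM, and for *lldP*, at 1187 CPM against 7293 and 7033 CPM. Without it the log2 fold change was -3.74 for *gltA* and -3.12 for *lldP*. The adjusted p of these 8 genes lay between 0.00389 for *ctb* and 0.0103 for *lldP*. The locus UC78_1330, at 1306378 to 1306692 on the minus strand, was chosen for mention after its values were seen. It rose from 337.9 ± 100.5 to 3368 ± 572.3 CPM, with a log2 fold change of 3.35 and an adjusted p of 0.00389, and it lies beside *katA*, which runs from 1306863 to 1308287 on the plus strand.

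**Figure D2:**
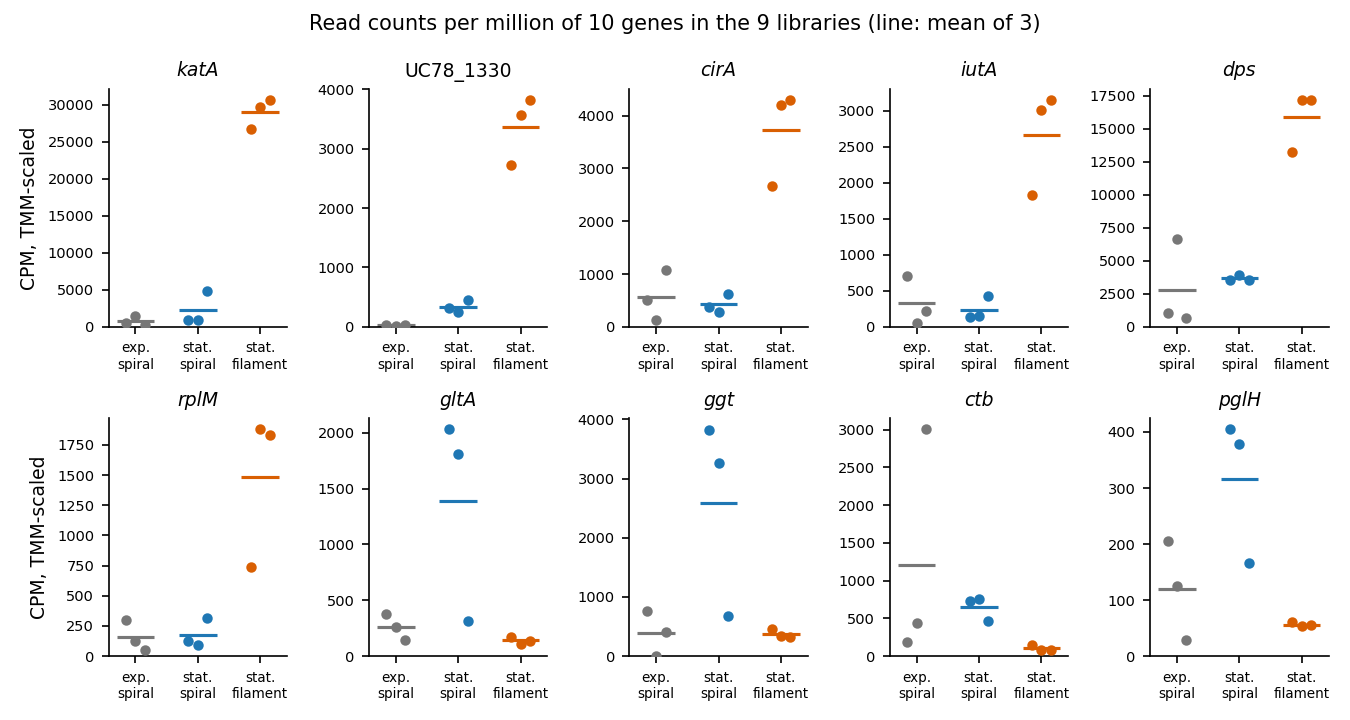
TMM-scaled CPM of 10 genes in each library, with 1 point per library and a line at the mean of the 3 libraries of a group. *katA* averages 737.1 CPM in exponential spirals, 2243 in stationary spirals and 29010 in filaments, while *gltA* averages 261, 1387 and 141.7 CPM.

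These values come from a fit to the 6 stationary libraries, an alternative planned before the data were examined, and the decision to lead with it and to name genes from it was made after. In that fit 691 of 1557 genes passed (edgeR, Benjamini-Hochberg), 355 higher and 336 lower in filaments, and 278 and 257 of these differed at least 2-fold. The planned fit to all 9 libraries, with the exponential spirals in the estimate of the spread, called 0 of 1582 genes in edgeR, with 360 at an unadjusted p under 0.05. DESeq2 called 246 genes on the same 9 libraries and limma-voom 0. Camera called 7 lists in that fit with its preset correlation and 0 with an estimated correlation. The adjusted p in the 9-library fit was 0.0936 both for *katA* (log2 fold change 3.69) and for UC78_1330 (3.32). It called 121 genes without exponential replicate 2, 302 without exponential replicate 3 and 12 without stationary spiral replicate 3. In the 6-library fit the count was 459 without stationary spiral replicate 1, 413 without replicate 2, 432 without filament replicate 2 and 412 without filament replicate 3. Without stationary spiral replicate 3 it was 871, and without filament replicate 1 it was 748. It was 1162 without both stationary spiral replicate 3 and filament replicate 1, a setting added after these libraries were seen to lie between the groups. Scaling by total count called 181 genes higher and 460 lower, so the share called higher was 28.2% in place of 51.4%. In 902 of 1582 genes, 57.0%, all 3 filament libraries lay above or all 3 below the stationary spirals (439 and 463 genes). Chance gives 10% for groups of equal spread.

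**Figure D3:**
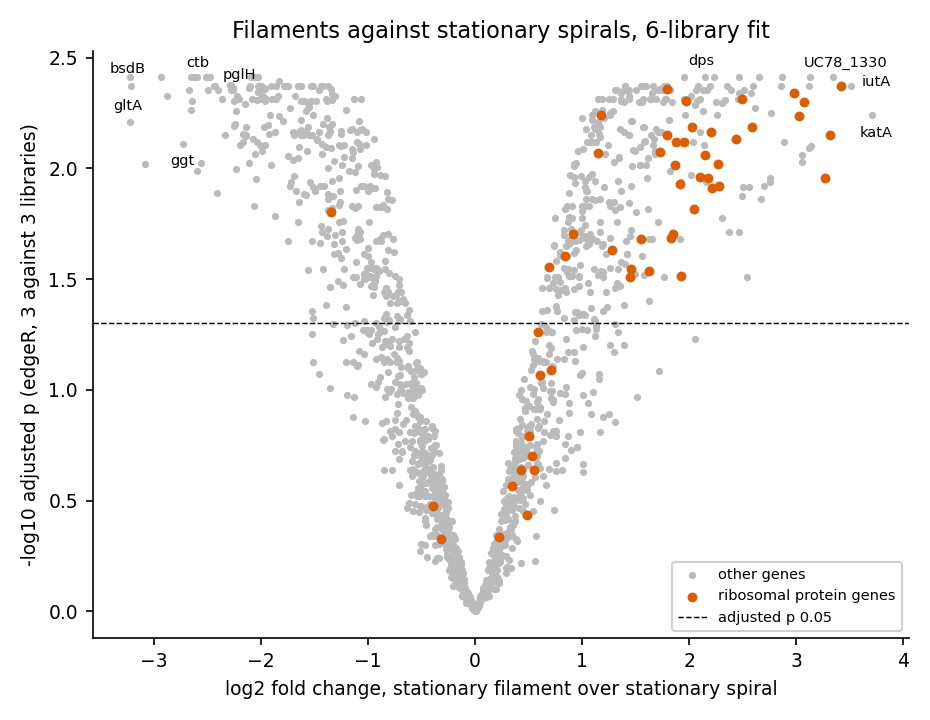
Log2 fold change of filaments over stationary spirals (x axis) against -log10 of the edgeR adjusted p (y axis, no unit) for 1557 genes in the 6-library fit, with ribosomal protein genes in orange and a dashed line at an adjusted p of 0.05. Of the 52 ribosomal protein genes, 39 lie above the line on the right and 1 on the left.

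In this fit, where 691 of 1557 genes passed, the largest list, that of ribosomal protein genes, also had the most changed members. Of 52 measured, 39 rose and 1 fell in filaments, 40 and 1 when adjusted over the list alone, and the median log2 fold change was 1.81. *rplD* rose from 52.22 ± 29.13 to 413.5 ± 184.9 CPM and *rpsT* from 10.82 ± 2.67 to 60.13 ± 27.39 CPM (n = 3 each). The set test camera gave this list an adjusted p of 1.28e-10 with its preset correlation, and adjusted p = 0.707 with an estimated correlation. The list of aminoacyl-tRNA synthetases, the enzymes that charge tRNAs, also held *gatB*, of an amidotransferase that acts on charged tRNAs. Of its 23 genes, 12 rose and 2 fell (13 and 2 adjusted over the list alone). *cysS* had a log2 fold change of 2.13, *aspS* 1.95 and *proS* 1.15. Camera returned an adjusted p of 0.0198 for this list and adjusted p = 0.707 with an estimated correlation. It was 0.0549 without stationary spiral replicate 3 and ranged from 0.00878 to 0.707 over 9 alternatives.

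Some genes for central carbon metabolism, nutrient uptake and respiration fell in filaments. In the list of the tricarboxylic acid cycle and pyruvate metabolism, 5 of 12 genes fell and 1 rose (7 and 1 adjusted over the list alone), and camera gave an adjusted p of 0.115, or adjusted p = 0.807 with an estimated correlation. Besides *gltA* and *lldP*, the acetate pathway genes *pta* and *ackA* fell, from 1022 ± 424.5 to 255 ± 18.95 CPM and from 438 ± 230.3 to 89.9 ± 1.5 CPM (n = 3 each), with *ackA* at 182.6 CPM in stationary spiral replicate 3 and 501.7 and 629.8 CPM in replicates 1 and 2. In the list of amino acid and C4-dicarboxylate uptake and catabolism, 6 of 13 genes fell and 0 rose (7 and 0 adjusted over the list alone). *peb1A*, an aspartate and glutamate binding protein, fell by 2.21 and the serine transporter gene *sdaC* by 1.97 on the log2 scale. The camera adjusted p was 0.0227, and adjusted p = 0.743 with an estimated correlation. It was 0.0706 without stationary spiral replicate 1, 0.052 without replicate 2 and 0.065 without filament replicate 1, and ranged from 0.000934 to 0.743 over 9 alternatives. In the Nuo respiratory complex, 5 of 7 genes fell and 0 rose (6 and 1 adjusted over the list alone), among them *nuoN* by 1.39 and *nuoL* by 1.13 on the log2 scale. Camera gave that list an adjusted p of 0.0536, and adjusted p = 0.707 with an estimated correlation. Other respiratory lists did not fall. Of 15 genes for respiration with alternative donors and acceptors 3 rose and 0 fell, and of 9 ATP synthase genes 2 rose and 1 fell. Their camera adjusted p was 0.362 and 0.857, and adjusted p = 0.807 and 0.889 with an estimated correlation.

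Protein N-glycosylation genes, which build and transfer the glycan that *C. jejuni* attaches to periplasmic proteins, were lower in filaments in 6 of 9 cases, the same number as adjusted over the list alone. *pglH* fell from 316.5 ± 131.1 to 56.14 ± 3.44 CPM and *pglI* from 110.9 ± 33.01 to 24.73 ± 6.67 CPM (n = 3 each). The camera adjusted p was 0.0108, and adjusted p = 0.707 with an estimated correlation. Only 4 genes of the fixed list of iron and haem uptake matched by symbol, and all 4 fell (4 adjusted over the list alone). They included *fur*, the gene of a regulator of iron uptake and not itself an uptake gene. The other names of the list had no match, and *iutA* and *cirA*, which are outside it, rose. The list therefore does not show the direction of iron uptake genes as a whole. *exbD* fell by 1.75, *feoB*, a ferrous iron transporter, by 1.50 and *exbB* by 1.37 on the log2 scale. Camera gave this list an adjusted p of 0.0536, and adjusted p = 0.707 with an estimated correlation. In oxidative and nitrosative stress defence, 3 of 10 genes rose and 1 fell (3 and 3 adjusted over the list alone). They included *katA* and *dps*, a DNA-binding iron storage protein, which rose from 3669 ± 190.6 to 15870 ± 2257 CPM, and the fall was that of *ctb*. For this list camera returned an adjusted p of 0.651, and adjusted p = 0.807 with an estimated correlation.

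The lists for dividing the cell, shaping it and replicating its chromosome were not called. Only 5 genes of the fixed cell division list matched by symbol. Most of its names, among them *minC*, *minD* and *minE*, were thus not measured. Of the 5 genes, 1 rose (1 adjusted over the list alone), which was *mraY*, a peptidoglycan precursor enzyme, with a log2 fold change of 1.82. *ftsZ*, the gene of the division ring protein, was at 1361 ± 331.5 CPM in stationary spirals and 1090 ± 58.56 CPM in filaments (n = 3 each), with a log2 fold change of -0.28 and an adjusted p of 0.391. That p was 0.042 without stationary spiral replicate 3 and ranged from 0.00113 to 0.753 over 16 alternatives. *ftsA* and *ftsY* had log2 fold changes of -0.25 and 0.45 with adjusted p of 0.342 and 0.181, which ranged from 0.0128 to 0.567 and from 0.0108 to 0.654 over 16 alternatives. The camera adjusted p of the list was 0.764, and adjusted p = 0.811 with an estimated correlation. Of 14 genes for peptidoglycan and cell shape, 2 rose and 2 fell (2 and 1 adjusted over the list alone), with log2 fold changes of 1.53 for *murA* and 1.44 for *murC*. Camera gave an adjusted p of 0.651, and adjusted p = 0.807 with an estimated correlation. Of 13 genes for chromosome replication and segregation, 4 rose and 2 fell (5 and 3 adjusted over the list alone). *dnaE*, of DNA polymerase III, rose by 2.47, topoisomerase gene *topA* by 1.83 and ribonucleotide reductase gene *nrdA* by 1.68 on the log2 scale, while *parB* fell by 1.07. Camera gave an adjusted p of 0.573, and adjusted p = 0.743 with an estimated correlation.

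Among chaperones and proteases, 7 of 20 genes rose and 3 fell (7 and 3 adjusted over the list alone), with a camera adjusted p of 0.464 and adjusted p = 0.707 with an estimated correlation. *cbpA* rose by 1.76, whereas *clpS* and *clpA*, the adaptor and the ATPase of a protease, fell by 2.28 and 1.64 on the log2 scale. *dnaK* had a log2 fold change of 0.23 (adjusted p = 0.47, from 0.0399 to 0.85 over 16 alternatives) and *recA* 0.11 (adjusted p = 0.746), and both turned negative under total-count scaling, at -0.11 and -0.21. *csrA* had a log2 fold change of -0.73 (adjusted p = 0.0719). That p was 0.0122 without stationary spiral replicate 3 and 0.0394 without filament replicate 1, and ranged from 1.84e-05 to 0.19 over 16 alternatives. In the list of filament genes of the flagellum, 2 of 7 rose and 2 fell (2 and 2 adjusted over the list alone), with a camera adjusted p of 0.754 and adjusted p = 0.807 with an estimated correlation. *fliD*, the filament cap gene, rose by 1.40 on the log2 scale. The 3 genes named *flaA* differed in sign. *flaA_1* fell by 0.81 (adjusted p = 0.0138), *flaA_2* fell by 1.38 and *flaA_3* rose by 1.57, but 53.6% of the reads of *flaA_2* and 52.4% of those of *flaA_3* were unique, so the values of these copies are uncertain. The adjusted p of *flaA_1* was 0.0592 without stationary spiral replicate 1, 0.0583 without filament replicate 2 and 0.0742 without filament replicate 3, and ranged from 1.84e-06 to 0.0742 over 16 alternatives.

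**Figure D4:**
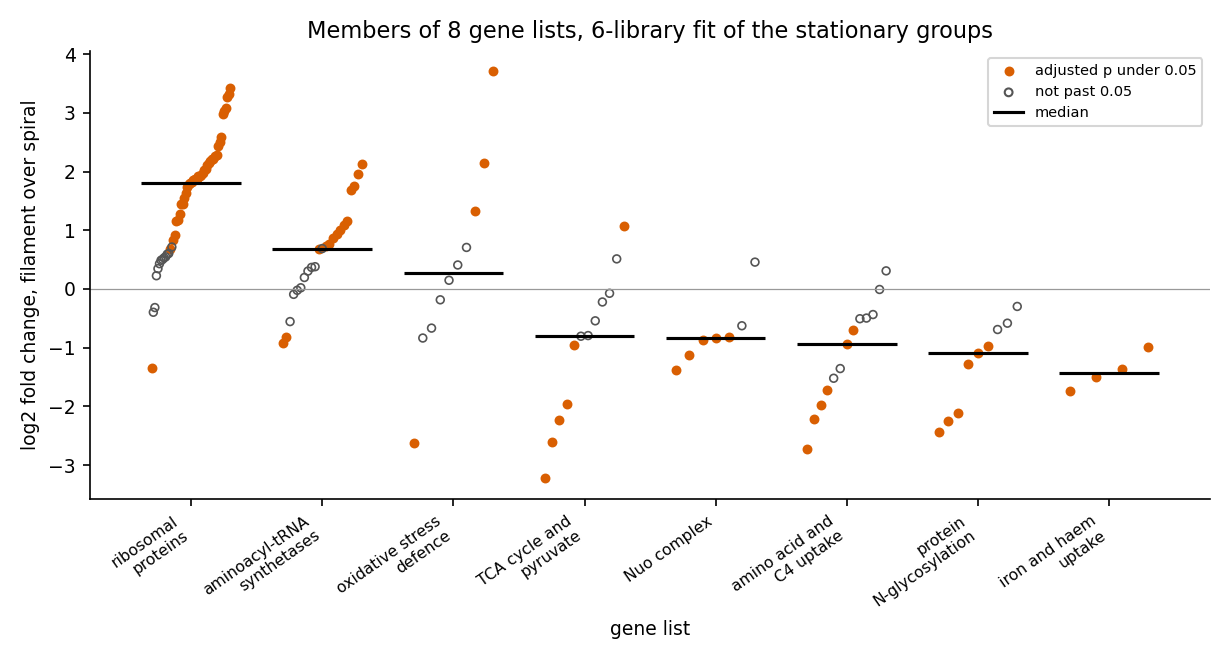
Log2 fold change of filaments over stationary spirals (y axis) for each member of 8 gene lists fixed beforehand (x axis), with filled points for genes past an adjusted p of 0.05, open points for the others and a line at the list median. The median of the ribosomal protein list is 1.81, and all 4 genes of the iron and haem uptake list, among them the regulator gene *fur*, lie below 0. That list held only genes matched by symbol, and *iutA* and *cirA*, which rose, are outside it.

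The second comparison set filaments against exponential spirals, that is against short cells in another growth phase. *katA* again had the largest rise among genes with a symbol, from 737.1 ± 604.7 to 29010 ± 2011 CPM (n = 3 each), with a log2 fold change of 5.30, an SE of 1.08 and an adjusted p of 0.0166. The ferritin gene *ftn* rose from 795.1 ± 271 to 7229 ± 2492 CPM, the cysteine desulfurase gene *nifS* from 462.9 ± 161.1 to 6111 ± 1431 CPM and *ssrA* from 5861 ± 3917 to 53240 ± 2044 CPM. The log2 fold changes were 4.53 for *tpd*, 3.72 for *nifS*, 3.23 for *futA1*, 3.22 for *rplM*, 3.19 for *rpsJ*, 3.18 for *ftn* and 3.18 for *ssrA*. UC78_1330 had a higher value than any of these, at 7.20 with an adjusted p of 0.00176, on means of 22.46 ± 13.77 and 3368 ± 572.3 CPM. Among genes with a symbol whose groups did not overlap, the largest falls had log2 fold changes of -4.33 for the transporter gene *oppD*, -4.08 for the phosphate transporter gene *pstC*, -3.96 for *kdgR*, -3.93 for the shikimate kinase gene *aroK*, -3.92 for *yigZ*, -3.74 for *legG*, -3.73 for the flagellar hook gene *flgE_1* and -3.69 for *xecE*. Many of these values depended on 1 exponential library. Without replicate 1 the log2 fold change was -1.92 for *pstC*, -2.36 for *aroK* and 4.11 for *rplM*. Without replicate 2 it was -3.03 for *oppD*, -2.14 for *flgE_1*, 6.23 for *katA* and 3.84 for *ssrA*, and without replicate 3 it was -2.60 for *kdgR* and -2.70 for *xecE*. It was 7.81 for UC78_1330 without replicate 1, and -4.88 for *kdgR* without filament replicate 1.

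In edgeR, 112 genes rose and 196 fell out of 1582, all of them by at least 2-fold, and 631 had an unadjusted p under 0.05. All 3 filament libraries lay above the exponential spirals in 309 genes and below them in 284, together 37.5%. Chance gives 10% for groups of equal spread, which these were not, and the chance share at unequal spread was not computed. Of the calls, 36.4% were higher, against 11.0% under total-count and 25% under upper-quartile scaling, which moved the median of all genes by -0.53 and -0.26 on the log2 scale. DESeq2 called 556 genes, and edgeR on the 6 libraries of these groups alone called 0, with 493 at an unadjusted p under 0.05. The count was 632 without exponential replicate 2, 140 and 130 without stationary spiral replicates 1 and 2, 40 without filament replicate 1 and 1 without filament replicate 2 or 3, and that 1 gene was UC78_1330. In simulated data with the spread of each group, 10.28% of unchanged genes in this comparison had an unadjusted p under 0.05, and 3 unchanged genes passed the adjusted threshold on average.

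Ribosomal protein genes were also higher in filaments than in exponential spirals. Of 52, 20 rose and 0 fell (29 and 0 adjusted over the list alone), with a median log2 fold change of 1.81. *rplV* rose from 472.9 ± 252.7 to 4123 ± 472.3 CPM, *rpmA* from 122.1 ± 28.88 to 1010 ± 488 CPM and *rplF* from 225.5 ± 77.13 to 1589 ± 124.1 CPM (n = 3 each). Camera gave an adjusted p of 4.24e-13, and adjusted p = 0.68 with an estimated correlation. Of 23 genes in the list of aminoacyl-tRNA synthetases, 3 rose (3 adjusted over the list alone). These were *aspS*, *gltX* and the amidotransferase gene *gatB*, with log2 fold changes of 2.39, 2.10 and 1.97, and *gatB* was at 2.57 without exponential replicate 2. Camera returned an adjusted p of 0.00052, and adjusted p = 0.68 with an estimated correlation.

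Protein N-glycosylation genes fell in 4 of 10 cases (5 adjusted over the list alone), by 2.12 for *pglI*, 1.96 for *pglA*, 1.78 for the oligosaccharyltransferase gene *pglB* and 1.45 for *pglJ* on the log2 scale. Without exponential replicate 1 the values were -1.51 for *pglI* and -1.10 for *pglA*, which lost its call (adjusted p = 0.0677, in a range from 0.00601 to 0.166 over 21 alternatives). For this list camera returned an adjusted p of 0.0402, and adjusted p = 0.681 with an estimated correlation. It was 0.19 without exponential replicate 1, 0.108 without replicate 2, 0.0663 without filament replicate 1 and 0.0569 without filament replicate 3, and ranged from 0.00273 to 0.681 over 13 alternatives. In the list of rod and hook genes of the flagellum, 4 of 9 fell and 0 rose (7 and 0 adjusted over the list alone). *flgG_2* fell by 3.70, *flgI* by 3.22 and *flgK* by 2.01 on the log2 scale, although the groups overlapped for *flgG_2* and *flgI*. These falls were carried in part by exponential replicate 2, without which the values were -2.81, -0.68 and -0.95, and *flgI* and *flgK* lost their calls (adjusted p = 0.285 and 0.0672, in ranges from 0.00384 to 0.285 and from 0.00382 to 0.18 over 21 alternatives). Camera gave that list an adjusted p of 0.271, and adjusted p = 0.694 with an estimated correlation. *flaA_1* fell by 3.32 (adjusted p = 0.0229), with exponential levels of 893.1, 8130 and 1914 CPM, and its log2 fold change was -1.88 without exponential replicate 2. *flaA_2* had a log2 fold change of -3.07 (adjusted p = 0.0613), which was -0.25 without exponential replicate 2 and passed at -3.53 and -3.59 without replicates 1 and 3, and *flaA_3* of -1.38 (adjusted p = 0.454), which was 3.14 without exponential replicate 2, with an adjusted p of 0.00678 in a range from 0.00678 to 0.906 over 20 alternatives.

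For 3 further lists camera gave a call although few members passed. Of 6 chemotaxis genes 2 rose (4 adjusted over the list alone), *cheV* by a log2 fold change of 1.88 and *cheW* by 1.46, with a camera adjusted p of 0.0291 and adjusted p = 0.68 with an estimated correlation. Of 9 ATP synthase genes 1 rose, *atpG* with a log2 fold change of 1.59 (0 adjusted over the list alone), with a camera adjusted p of 0.0348 and adjusted p = 0.68 with an estimated correlation. Of 15 genes for respiration with alternative donors and acceptors 1 rose, the fumarate reductase gene *frdC* with 1.87 (0 adjusted over the list alone), with a camera adjusted p of 0.0252 and adjusted p = 0.694 with an estimated correlation. Without exponential replicate 1 the adjusted p was 0.104 for each of these 3 lists. Without exponential replicate 3 it was 0.0523 for ATP synthase and 0.184 for respiration. Over 13 alternatives each it ranged from 0.0063 to 0.68, from 0.0125 to 0.68 and from 0.000276 to 0.694. *ftsZ* had a log2 fold change of 1.17 (adjusted p = 0.164), *recA* 0.98 (adjusted p = 0.135), *dnaK* -0.91 (adjusted p = 0.359) and *csrA* -0.15 (adjusted p = 0.853). Without exponential replicate 2 *ftsZ* was at 2.03 and *recA* at 1.21, with adjusted p of 0.0124 and 0.0492, in ranges from 0.0124 to 0.337 and from 0.0372 to 0.462 over 21 alternatives, and *dnaK* was at -0.06.

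The third comparison set stationary against exponential spirals and so asked what growth phase changed in cells of the same shape. *nuoK*, a subunit gene of the Nuo respiratory complex, rose from 16.23 ± 10.15 to 114.3 ± 5.77 CPM (n = 3 each), with a log2 fold change of 2.74 (3.42 without exponential replicate 1), an SE of 0.54 and an adjusted p of 0.0459. UC78_1330 rose from 22.46 ± 13.77 to 337.9 ± 100.5 CPM, with a log2 fold change of 3.89 and an adjusted p of 0.0385. *legI* and *legG*, named for the synthesis of legionaminic acid, a sugar found on flagellin, fell from 452 ± 315.4 to 51.92 ± 2.47 CPM and from 349.8 ± 197 to 54.9 ± 9.72 CPM. They are neighbours at 1239754 to 1240758 and 1240751 to 1241905, and *epsN* at 1237860 to 1239005 fell by 2.16 on the log2 scale. The phosphate transporter gene *pstA* fell by 2.21, the peptide transporter gene *dtpT_1* by 2.30, *lolD_2* by 2.17 and the tRNA dihydrouridine synthase gene *dusC* by 2.00.

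In edgeR 2 genes rose and 14 fell out of 1582, and 429 had an unadjusted p under 0.05. All 3 stationary spiral libraries lay above the exponential ones in 171 genes and below them in 196, together 23.2%. Groups of equal spread give 10% by chance. The wider spread of the exponential libraries can raise that share in unchanged genes, so whether 23.2% exceeds chance is not known. The count of calls was 98, 353 and 124 without exponential replicates 1, 2 and 3, and 0 without any 1 of stationary spiral replicates 1, 2 and 3 or filament replicates 1, 2 and 3. DESeq2 called 306 genes, limma-voom 0, upper-quartile scaling 7, total-count scaling 0 with 328 at an unadjusted p under 0.05, and the 6 libraries of these groups alone 0 with 248. In simulated data with the spread of each group, 11.17% of unchanged genes in this comparison had an unadjusted p under 0.05, and 5.2 unchanged genes passed the adjusted threshold on average. In 20 simulations of unchanged groups against the exponential libraries this comparison gave 0 to 17 calls, so the 16 calls lie within the range found without any change.

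Camera with its preset correlation called 5 lists as higher in stationary spirals, and 1 gene of these lists, *nuoK*, passed over all genes. All 12 genes of the tricarboxylic acid cycle and pyruvate metabolism had positive fold changes, 0 passed and 5 passed when adjusted over the list alone. *gltA* was at 261 ± 115.9 and 1387 ± 934.5 CPM (n = 3 each; log2 fold change 2.40, adjusted p = 0.0976), with *sucC* at 1.54 and *mdh* at 1.59. Without exponential replicate 2 *sucC* and *mdh* were at 1.84 and 2.13 and passed. That list also held *porA* as fixed by name, at 2.68, although in *C. jejuni* the name belongs to the major outer-membrane porin. Camera gave it an adjusted p of 4.98e-05, and adjusted p = 0.587 with an estimated correlation. For the Nuo complex, all 7 fold changes were positive and 1 gene passed (1 adjusted over the list alone), with *nuoI* at a log2 fold change of 1.48, *nuoN* at 0.97 and *nuoD* at 0.86, and *nuoI* at 2.51 and past the threshold without exponential replicate 1. Its camera adjusted p was 0.00102, and adjusted p = 0.587 with an estimated correlation.

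The other lists called were ATP synthase (9 genes, 0 passed and 3 adjusted over the list alone), respiration with alternative donors and acceptors (15 genes, 0 and 0) and amino acid and C4-dicarboxylate uptake and catabolism (13 genes, 0 and 0). Fold changes were positive in 7, 11 and 8 genes of these lists and negative in 2, 4 and 5. Log2 fold changes were 1.82 for *atpG*, 1.62 for *atpC*, 1.95 for *atpF_1* and 1.13 for *atpD_2*. They were 1.66 for *frdB_1*, and 1.43 and 1.55 for the hydrogenase genes *hydB* and *hydC*. They were 1.34 for *putA*, 1.56 for *sdaC*, 1.33 for *dcuB_1* and 2.71 for *ggt*, which had 2 reads in exponential replicate 2. Without that library *atpG*, *atpC* and *atpF_1* were at 2.09, 2.21 and 2.61, *frdB_1*, *hydB* and *hydC* at 2.36, 2.20 and 2.70, and *sdaC* and *dcuB_1* at 2.32 and 1.83, and all 8 passed. *atpG* also passed without exponential replicate 3, at 1.44. *ggt* was at 2.12 without exponential replicate 2 and at 3.50 without replicate 1, and did not pass. The camera adjusted p was 0.0209, 0.0209 and 0.0306 for the 3 lists, and adjusted p = 0.587, 0.78 and 0.587 with an estimated correlation. Without exponential replicate 1 it was 0.0951, 0.127 and 0.226. For respiration it was 0.439 without exponential replicate 3 and 0.0695 without stationary spiral replicate 1, and for amino acid uptake 0.0695 without stationary spiral replicate 1. Over 13 alternatives each it ranged from 0.00956 to 0.587, from 0.000188 to 0.78 and from 0.00822 to 0.587. *ftsZ* had a log2 fold change of 1.49 (adjusted p = 0.155), *katA* 1.60 (adjusted p = 0.269), *recA* 0.91 (adjusted p = 0.212), *dnaK* -1.10 (adjusted p = 0.324) and *csrA* 0.63 (adjusted p = 0.44). Without exponential replicate 2 *ftsZ* was at 2.30 with an adjusted p of 0.0181, in a range from 0.0181 to 0.402 over 21 alternatives, *katA* at 2.50 and *dnaK* at -0.30. Without stationary spiral replicate 3 *katA* was at 0.33, and without exponential replicate 1 *csrA* was at 0.11. *flaA_1*, *flaA_2* and *flaA_3* had -2.46, -1.65 and -2.92 (adjusted p = 0.106, 0.302 and 0.206), and without exponential replicate 2 they were -1.08, 1.12 and 1.56. *flaA_1* passed without exponential replicate 1, at -2.96.

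All 16 genes called between stationary and exponential spirals were also called between filaments and exponential spirals, 2 higher and 14 lower in both. Independent lists of these sizes would share 0.142 higher and 1.73 lower genes. Both comparisons used the same 3 exponential libraries, and unchanged groups simulated against them shared 3.05 calls on average (0 to 9 in 20 simulations). However, those simulations called 4.75 and 4.9 genes on average in the 2 comparisons, against 16 and 308 in the data. The simulated count of shared calls is therefore no measure of what shared controls give with 308 calls. The fold changes of the 2 comparisons correlated at 0.674 over genes, against 0.904 (0.892 to 0.912) in the simulations. Their covariance was 1.24, against 0.625 (0.559 to 0.675), and they had the same sign in 76.7% of genes, against 85.7%. Because 3 control libraries cannot be split into 2 sets of at least 2, part of the overlap may come from the shared controls. The number of shared calls was 80, 238 and 89 without exponential replicates 1, 2 and 3 and 0 without any 1 of the 6 stationary libraries.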

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

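Of the tests in this part, those on gene length, on distance from the replication origin and on other splits of the libraries were chosen before the results were seen, and the others after. Exponential spiral replicate 1 had a flat read profile, with an interquartile range of read density over genes of 1.05 on the log2 scale. If reads from genomic DNA caused this, genes near silent elsewhere should have kept much of the median density. They had 0.529 of it in this library against 0.0748 to 0.208 in the others. Any cause of a flat profile would raise this value, so the test cannot tell genomic DNA from other causes. Genomic DNA stays possible. Growth phase did not account for it, since exponential replicate 3 had an interquartile range of 2.795 on the log2 scale. DNA of replicating cells would have given a density that fell with distance from the origin, taken at *dnaA* and not checked on a genome, and the rank correlation was -0.02 over near-silent genes and -0.14 over all genes, against -0.05 to 0.01 in the other libraries. The near-silent genes thus did not show the predicted fall. Their median was 0.529 of the library median in the 33 nearest to *dnaA* and 0.538 in the 48 farthest from it. Over all genes the correlation was lower than in any other library, which goes the other way. The test therefore does not settle whether that DNA came from replicating cells. Degraded RNA stays open.

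In exponential spiral replicate 2, 56 genes had 3 reads or fewer although their mean in the stationary libraries was at least 20 CPM, among them the 8 neighbours from *fcl* to *tagB* at 1344849 to 1356386 and the 7 genes up to *ggt* at 43716 to 52826. Another strain or a deletion variant in this culture should have left neighbouring genes without reads. The data held 28 pairs of neighbours, against at most 9 in random sets of the same size, so such a variant may account for the pattern. Neighbouring genes can also be silenced together, and random sets do not allow for that. The test therefore cannot tell a variant from joint regulation of neighbours. Growth phase did not account for it, because 92.9% of the 56 genes were at 20 CPM or more in both other exponential libraries. Sampling depth gave 8.93e-08 such genes. None of the 16 genes called between stationary and exponential spirals or of the 308 called between filaments and exponential spirals was among the 56. The 56 were chosen for few reads in exponential replicate 2, while most were higher in the other exponential libraries. That spread within the group by itself hinders a call, so their absence does not show that this library left the calls unaffected. Without exponential replicate 2 the counts of calls were 353 and 632, in place of 16 and 308.

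Ribosomal protein genes were higher in filaments than in stationary spirals, by a median of 1.81 on the log2 scale. A bias by gene length would have moved other genes of matched length as well, and their median was 0.04, so it did not account for the rise. A return of filament cells toward the exponential state was to keep the ribosomal share of reads at or below the highest exponential value. In 3 of 3 filament libraries it lay above that value. However, the share was 2.6%, 2.75% and 1.06% in exponential replicates 1, 2 and 3, and 2.19%, 2.09% and 4.31% in stationary spirals. The exponential libraries were thus not consistently above the stationary spirals, and they differed strongly from each other. This test therefore cannot exclude that explanation. A transcriptional difference tied to cell shape was named in the design and is a hypothesis that stays open. An effect of the filtration that parted the cells was not tested.

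With 3 libraries in each group there are 10 ways to split the 6 libraries of a comparison, too few for a share under 0.05. The real split gave 16 calls between stationary and exponential spirals, 308 between filaments and exponential spirals and 691 between filaments and stationary spirals in the 6-library fit, and the highest other split gave 0, so that 1, 1 and 1 of 10 splits reached the real count. In the 9-library fit of filaments against stationary spirals the real count was 0 and 10 of 10 splits reached it, as any split must. At an unadjusted p under 0.05 in edgeR the real split gave 360 genes and the highest other split 57.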

How the results depend on the processing

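The unique reads, quality weights, near-0 genes, 4-library setting and all alternatives of the 6-library fit were tests chosen after the results were seen, and the others were planned. The 16 genes called between stationary and exponential spirals became 7 under upper-quartile scaling, 0 under total count, 306 in DESeq2, 0 in limma-voom, 6 without a filter, 0 in the 6 libraries alone, 2 with quality weights and 30 without the near-0 genes of exponential replicate 2. Leaving out 1 library gave 0 to 353. The 308 genes between filaments and exponential spirals became 556 in DESeq2 and 0 in the 6 libraries alone, and leaving out 1 library gave 1 to 632. The 0 between filaments and stationary spirals became 246 in DESeq2, 691 in the 6 libraries and 1149 with quality weights, and leaving out 1 library gave 0 to 302. The 691 of the 6-library fit became 1162 in 4 libraries, and leaving out 1 gave 412 to 871. The 16 shared genes ranged from 0 to 238.

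Of the 5, 6 and 7 list calls in the 9-library fit and the 4 in the 6-library fit, 0 remained with an estimated correlation. Between filaments and stationary spirals 4 remained in the 6 libraries alone. Leaving out 1 library gave 2 to 11, 2 to 7, 4 to 6 and 3 to 4.

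With replicate number as a block, the 9-library fit called 0 genes between stationary and exponential spirals, 32 between filaments and exponential spirals, and 0 between filaments and stationary spirals. The 6-library fit called 691, of which 643 were among the 691 called without the block. Not every library correlated best with the library of its own number, with correlations from -0.3 to 0.15 between those of the same number, so they were not treated as paired.

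Named genes that changed sign were *flaA_2* (1.12 without exponential replicate 2, 0.13 with quality weights; -2.22 without replicate 3) and *flaA_3* (1.56 and -3.54 without replicates 2 and 3) between stationary and exponential spirals. Between filaments and exponential spirals *flaA_3* was 1.32 in limma-voom, 0.37 with the block, 1.72 with quality weights and 3.14 and -1.96 without exponential replicates 2 and 3, and *csrA* was 0.17 in limma-voom, 0.42 with quality weights, and -0.59, 0.23 and 0.1 without exponential replicates 1, 2 and 3. Between filaments and stationary spirals *dnaK* was -0.11 and *recA* -0.21 under total count, and *recA* was -0.1 without stationary spiral replicate 3 and 0.27 without replicate 1. In the 6-library fit these were -0.11 and -0.21, and -0.09 and 0.27, with -0.03 without filament replicate 3.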

Other observations

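The genes and tests in this part were chosen after their values were seen. They were picked because they rose or fell, and other members of their pathways were not tallied. Between filaments and stationary spirals in the 6-library fit, the ferritin gene *ftn* rose from 2102 to 7229 CPM (log2 fold change 1.81, adjusted p = 0.00603), *efeU*, named as an iron permease, from 237 to 1336 CPM (2.51, adjusted p = 0.00442) and *hmuU*, named as a haem permease, from 117.7 to 515 CPM (2.14, adjusted p = 0.00783). In contrast, all 4 genes of the fixed iron and haem uptake list fell, namely *feoB*, *exbB*, *exbD* and the regulator gene *fur*. The iron-sulfur cluster genes *nifS*, *iscU* and the ferredoxin gene *fdx* rose by log2 fold changes of 2.88, 2.10 and 2.47. Without stationary spiral replicate 3 the log2 fold change was 3.90 for *nifS* and 2.90 for *hmuU*. Iron-related genes thus moved in both directions, and no common direction was tested.

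Single genes picked in the same way included 4 named for fatty acid synthesis, with log2 fold changes of 1.73 for *accA*, 1.73 for *fabG*, 1.84 for *fabF* and 1.82 for *acpP*, and *cfa*, the gene of cyclopropane fatty acid synthase, rose from 43.82 to 270 CPM. Of genes named for the synthesis of leucine, branched-chain amino acids and pantothenate, *leuB* rose by 1.71, *leuC* by 2.13, *ilvE* by 2.05, *panB* by 2.60 and *panC* by 2.02 on the log2 scale. The chaperonin genes *groL* and *groS* rose by 1.92 and 2.50, and belong to the fixed list of chaperones and proteases, for which camera gave an adjusted p of 0.464, and adjusted p = 0.707 with an estimated correlation. Without stationary spiral replicate 3 the log2 fold change was 3.33 for *cfa*, 3.13 for *panB*, 2.82 for *panC*, 2.52 for *groL* and 3.47 for *groS*. The genes *ssrA* and *smpB*, partners in trans-translation, which frees stalled ribosomes, moved in opposite directions. Since *ssrA* was set beforehand as a sign of RNA depletion and quality, its rise is not read as a change of that pathway. *ssrA* rose from 18690 ± 3223 to 53240 ± 2044 CPM (n = 3 each; log2 fold change 1.55, adjusted p = 0.00424) and *smpB* fell from 446 ± 195.2 to 81.56 ± 17.56 CPM (log2 fold change -2.40, adjusted p = 0.00442). Over 16 alternatives the log2 fold change of *ssrA* was 1.24 to 1.67 and that of *smpB* -2.92 to -2.20.

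Ribosomal protein genes held 4.31% of gene reads in stationary spiral replicate 3, against 2.19% and 2.09% in the other 2, and 4.92%, 6.22% and 6.18% in the filaments. Positions were set over 750 genes at least 2-fold apart between stationary spiral replicates 1 and 2 (0) and filament replicates 2 and 3 (1). On the log2 scale stationary spiral replicate 3 lay at a median of 0.34 and filament replicate 1 at 0.74, so both lay between the groups on this measure. The genes were chosen for the gap between the other libraries, which by itself draws a left-out library inward. How far an ordinary replicate would be drawn was not computed. Incomplete separation of the cell types was not tested as a cause. Exponential spiral replicate 3 had 39 genes with 3 reads or fewer and a stationary mean of at least 20 CPM, with 2 pairs of neighbours among them and 1 gene shared with exponential replicate 2.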
